A study of Drosophila melanogaster with 21 samples.

How the data were processed

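RNA of the lower reproductive tract of Drosophila melanogaster females was measured on 21 single-colour oligonucleotide arrays. Per the labels, females were 3 days old, were kept at 23 C, and 12 to 40 of them were pooled for each array. The labels place 5 arrays with unmated females, 6 with females at 0 h after mating, 4 at 3 h, 3 at 6 h and 3 at 24 h. The p-values of single probe sets measure the spread between these pools. They take the arrays as independent, although arrays of 1 processing run, defined below, had a correlation of 0.311. Within a group, no pair of arrays had more than 0.507% of its values identical, and each array was counted as 1 replicate.

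The deposited values are linear intensity of each probe set. The submitters' processing notes name RMA without a version. The deposited intensity values do not have the form of RMA output: they are not on a log scale, their quartiles differ between arrays, and all arrays share a 2% trimmed mean. How the authors summarised probes into a signal is therefore not settled, and its software is not given in the sources used here. The median signal of an array lay between 35.6 and 57.7. The number of arrays limits the precision of each comparison.

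From there, log2 of the signal was taken with no pseudocount and no further scaling. The table holds 14010 probe sets, of which 44 control probe sets were left out and 13966 were tested. The platform annotation gave 12443 of these 1 gene symbol, 327 several and 1196 none. Symbols of 12394 probe sets were updated through their gene identifier with the RefSeq annotation of Release 6 plus ISO1 MT, which was used for names only. A gene was represented by its probe set with the highest mean over all arrays, giving 10844 genes. Probe sets with several symbols were not named.

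Differences were tested with limma 3.58.1 in R 4.3.3. A single linear model gave each of the 5 groups a mean over all 21 arrays, with moderated variances, 2-sided tests and Benjamini-Hochberg adjustment over probe sets within each comparison at a threshold of 0.05. Adjusted p-values of probe sets and genes come from this model, and those of gene lists from camera, described below, unless another test is named. Each mated time was compared with unmated females, and each time with the time before it. A total of 32 gene lists with at least 3 measured genes were tested with camera at a preset inter-gene correlation of 0.01, adjusted over lists within a comparison. Its p-values set the genes of a list against other genes. They do not measure the spread of a list mean between pools. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance 1 way, served as alternatives. Some members entered lists by a name pattern or an alias without belonging to them (Sp1, Sp7, Acp1, Acph-1, Arpc1 and lost), and nanos was not matched. The lists were kept as fixed and were also tested without these stray members.

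Named genes were chosen by rule. For each mated time against unmated females these were the 6 genes with the highest and the 6 with the lowest log2 change past the threshold, and up to 3 passing members of each list with the smallest p. For neighbouring times the rule took 3 and 3 genes, and for the whole course the 5 genes with the smallest p of the moderated F test. The comparisons, the lists, this rule and most alternatives were chosen before the data were examined.

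Array numbers in the labels fall into 6 blocks separated by gaps of more than 20, called processing runs here. This grouping was inferred from the numbers, and no label states it. Run 1 held 3 unmated arrays. Run 2 held 2 arrays at 3 h. Run 3 held 2 unmated arrays, 1 at 3 h and 1 at 24 h. Run 4 held 2 arrays at 0 h, 1 at 6 h and 1 at 24 h. Run 5 held 4 arrays at 0 h, 1 at 3 h and 1 at 6 h. Run 6 held 1 array at 6 h and 1 at 24 h. RNA integrity was read from control probe sets as the mean log2 ratio of 3' to 5' signal of the eIF-4a and GAPDH transcripts.

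Alternatives chosen beforehand were quantile normalization, median centring, removal of the dimmer probe sets, a fit of only the groups compared, run as a fixed or random block, a variance trend with robust moderation, array weights, 1 probe set per gene, a 1.5-fold minimum, and leaving out each array in turn. Chosen after seeing the data were log2 of signal plus 16, the 3' to 5' ratio as a covariate, removal of run 6, and the lists without strays.

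The procedure was tested on simulated data with 200 changed probe sets in each of 3 rounds. Noise was drawn independently for each probe set and array, with no processing run and no correlation between genes. The real arrays had a correlation of 0.311 within run, so these rates do not show recovery under such effects. Of 4-fold changes, 59.2% were recovered for 0 h against unmated, 53.7% for 3 h, 43.8% for 6 h and 42.3% for 24 h. Of 2-fold changes, 16.4%, 6.97%, 2.99% and 3.98% were recovered in the same order. Rounds of the list test were pooled over all comparisons. A simulated shift of 1 on the log2 scale was found in 21 of 21 rounds for the antimicrobial list, 21 for the germline list and 21 for the oxidative phosphorylation list. A shift of 0.5 was found in 7, 15 and 21 rounds. For 6 h against unmated alone, it was found in 0, 0 and 3 of 3 rounds in the same order.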

Results

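The arrays profiled the female lower reproductive tract, the tissue that receives sperm and seminal fluid, in unmated females (n = 5) and in mated females at 0 h (n = 6), 3 h (n = 4), 6 h (n = 3) and 24 h (n = 3) after mating. The comparisons ask which transcripts of this tissue differ after mating. On the brighter probe sets, the first principal component held 29.9% of the variance, and processing run accounted for 94.5% of that component against 23.5% for the groups. No run held unmated arrays together with 0 h or 6 h arrays. The mean log2 ratio of 3' to 5' signal of control transcripts, a sign of RNA integrity, was 3.90 ± 2.01 (SD, n = 5) in unmated females, 3.28 ± 1.30 (n = 6) at 0 h, 3.95 ± 1.12 (n = 4) at 3 h, 2.82 ± 0.73 (n = 3) at 6 h and 3.78 ± 1.48 (n = 3) at 24 h. The median log2 change of all probe sets against unmated females was -0.10 at 0 h, -0.14 at 3 h, -0.21 at 6 h and -0.10 at 24 h. Camera compares each list with the other genes. It so allows for a shift equal for all genes, but not for one that differs with signal level.

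At 3 h after mating a small set of genes differed sharply from unmated females, led by Send2, which encodes a spermathecal endopeptidase. Its mean log2 signal was 6.07 ± 1.40 (SD, n = 5) in unmated females and 13.28 ± 0.39 (n = 4) at 3 h, a 148-fold rise (log2 change 7.21, SE 0.66, adjusted p = 6.19e-06). Transcripts of jhamt, the methyltransferase of juvenile hormone synthesis, rose 29.8-fold (log2 change 4.90, SE 0.54, adjusted p = 7.18e-05). Its geometric mean signal in unmated females, 28.4, lay below the median of every array, so the size of this rise is uncertain; with log2 of signal plus 16 the change was 4.17. PGRP-SC2, a peptidoglycan-degrading amidase, rose 8.39-fold (log2 change 3.07, SE 0.39, adjusted p = 0.000433), and CAH8, of the carbonic anhydrase family, rose 13.2-fold (log2 change 3.73, SE 0.41, adjusted p = 7.18e-05). In all, 11 probe sets were higher and 5 lower at 3 h; 11 genes rose and 3 fell.

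Other rises at 3 h were those of CG17134 (log2 change 5.70, SE 0.95), CG18088 (5.09, SE 0.59) and CG11426 (3.12, SE 0.47). Their unmated signals were also low (6.65, 3.98 and 28.6), and with log2 of signal plus 16 the changes were 4.00, 2.93 and 2.53. CG42284 fell by 5.77 on the log2 scale (SE 0.50, adjusted p = 4.98e-06), from 8.81 ± 0.26 (SD, n = 5) to 3.04 ± 1.21 (n = 4). Its other, dimmer probe set had a log2 change of 0.33 (SE 0.63, adjusted p = 0.956). Cad87A, a cadherin, fell by 2.63 (SE 0.49, adjusted p = 0.0273) and CG34367 by 2.33 (SE 0.42, adjusted p = 0.0208). The other, dimmer probe set of CG34367 had a log2 change of -0.92 (SE 0.55, adjusted p = 0.754). At 3 h these fallen genes lay below the array medians, CG42284 at 8.24 and CG34367 at 15.5, so the sizes are uncertain; with log2 of signal plus 16 the changes were -4.18, -1.97 and -1.51. The call of CG17134 was lost without 3 h replicate 2 or 3 (adjusted p up to 0.0634). That of Cad87A was lost without unmated replicate 1, 3, 4 or 5 or 3 h replicate 1, 2 or 3 (adjusted p up to 0.150), and that of CG34367 without unmated replicate 1, 2, 4 or 5 or 3 h replicate 1, 3 or 4 (adjusted p up to 0.123). Leaving out 3 h replicate 2 left 7 probe sets higher, and leaving out unmated replicate 1, unmated replicate 4 or 3 h replicate 3 left 3 lower.

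Run 3 held arrays of both groups, and there the 3 h array differed from the mean of the 2 unmated arrays by 6.53 for Send2, 6.28 for jhamt, 3.78 for PGRP-SC2, 3.79 for CAH8, 4.69 for CG18088, 2.42 for CG17134, 1.83 for CG11426, -4.24 for CG42284, -2.20 for Cad87A and -2.15 for CG34367 on the log2 scale. With run as a block, 6 of the 10 named genes stayed past the threshold: Send2 (log2 change 7.43), jhamt (6.07), PGRP-SC2 (3.85), CAH8 (4.03), CG18088 (5.21) and CG42284 (-4.67). The block ended the calls of CG17134 (4.07), CG11426 (2.01), Cad87A (-2.67) and CG34367 (-2.33).

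**Figure D1:**
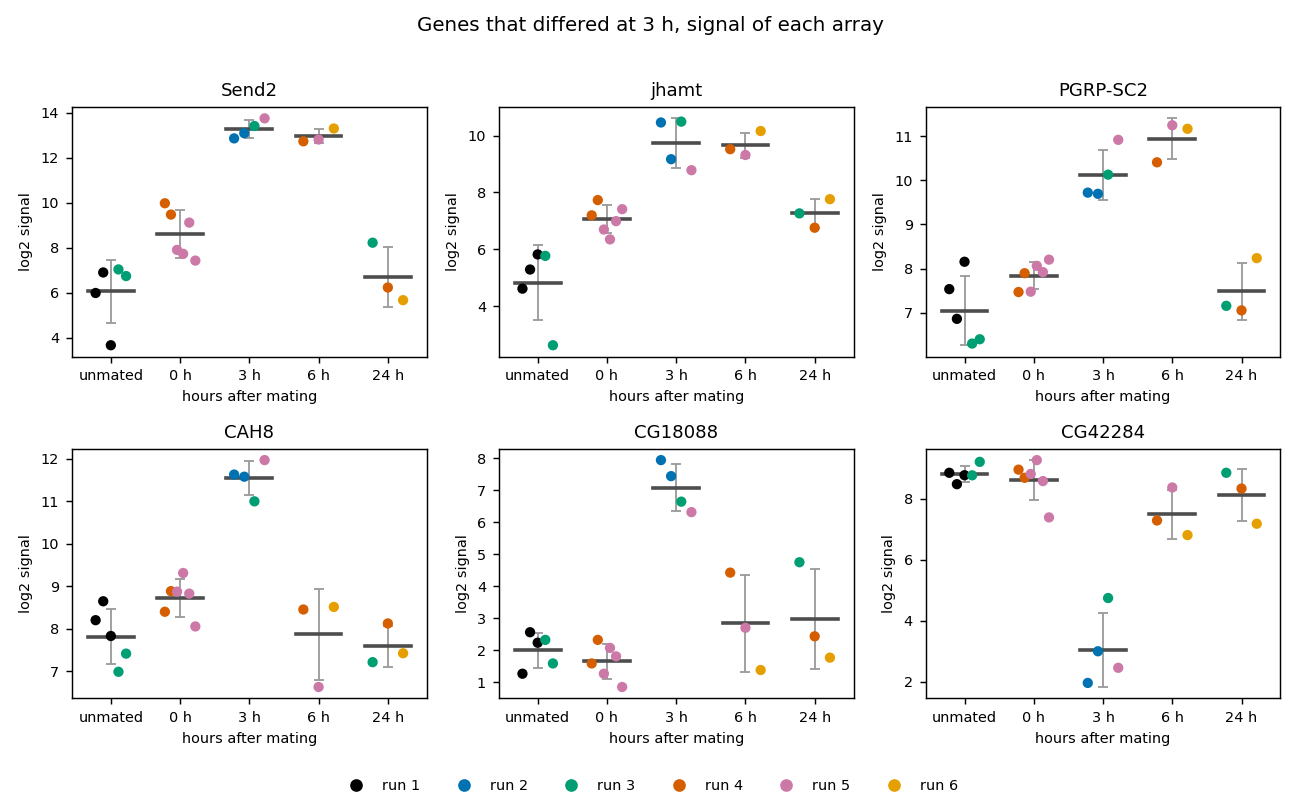
Log2 signal (vertical axes) of named genes by group (horizontal axes); each point is 1 array coloured by processing run, horizontal bars are group means and error bars are SD. Send2 lies at 13.28 on average at 3 h and 12.95 at 6 h against 6.07 in unmated females.

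Among the gene lists at 3 h, the 42 genes of the secretory pathway and endoplasmic reticulum chaperones were higher as a list (mean log2 change 0.20, 0.36 above other genes, camera adjusted p = 0.000855), with 32 members above 0 and none past the threshold alone. Genes known from the male accessory gland and ejaculatory duct were lower (30 genes, mean -0.77, adjusted p = 0.00415), as were ribosomal proteins (38 genes, mean -0.34, adjusted p = 0.0386), again with no member passing; adjusted over the list alone, 1 accessory gland gene fell. For these lists adjusted p = 0.676, 0.676 and 0.967 with an estimated correlation. None of the lists passed with run as a block, the means being 0.090, -0.87 and -0.19, and within run 3 they differed by 0.052, -0.94 and -0.25. Without the dimmer probe sets 3 of the 30 accessory gland genes were left and that call ended (adjusted p = 0.428). The accessory gland call was also lost without unmated replicate 5 (adjusted p = 0.0772), and the ribosomal call without unmated replicate 1, 2 or 5 or 3 h replicate 1, 2 or 4 (adjusted p up to 0.670). Quantile normalization ended the secretory, accessory gland and ribosomal calls (adjusted p = 0.159, 0.122 and 0.206). The ribosomal mean ranged from -0.59 without 3 h replicate 3 to -0.14 without replicate 1. The spermathecal and accessory gland protease list did not pass (7 genes, adjusted p = 0.961): Send2 rose, the list mean was 0.53 and the median -0.50, and camera placed it downwards.

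At 6 h after mating more genes passed than at 3 h in the fit without run: 85 rose and 127 fell (94 and 163 probe sets). With run as a block the order reversed, and fewer probe sets passed at 6 h than at 3 h. In that fit 1 of 29 named genes stayed past the threshold at 6 h, against 6 of 10 at 3 h. Send2 (118-fold, log2 change 6.88, SE 0.72, adjusted p = 0.000112), jhamt (28.6-fold, 4.84, SE 0.59), CG17134 (6.07, SE 1.03), CG11426 (2.97, SE 0.51) and PGRP-SC2 (3.90, SE 0.43) were again higher; with log2 of signal plus 16 the changes of jhamt, CG17134 and CG11426 were 4.11, 4.31 and 2.39. The log2 change at 6 h was 0.050 (SE 0.45) for CAH8 and 0.84 (SE 0.65) for CG18088, neither past the threshold. Lists of oocyte and DNA replication genes were higher, and lists of neuronal, blood cell, muscle, basement membrane and septate junction genes were lower in camera at its preset correlation. With an estimated correlation 0 of the 32 lists passed. Of the probe sets called, 7 higher and 1 lower were shared with 3 h.

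Of 30 germline and oocyte genes, 3 rose, 0 fell and 27 did not pass; adjusted over the list alone, 11 rose and 1 fell. The list's mean log2 change was 1.33, or 1.52 above other genes (camera adjusted p = 2.52e-06; adjusted p = 0.156 with an estimated correlation). The risen genes were swa (4.41, SE 0.93, adjusted p = 0.0195), needed to localise bicoid RNA in the oocyte, pgc (3.58, SE 0.81), which represses transcription in pole cells, and tor (2.07, SE 0.51), the receptor of the embryonic termini. Unmated signals were 11.2, 27.1 and 9.12, below the array medians, so the sizes are uncertain; with log2 of signal plus 16 the changes were 3.14, 2.94 and 1.18. A dimmer probe set of swa had a log2 change of -0.67 (SE 0.65, adjusted p = 0.637). The call of swa was lost without 6 h replicate 1 (adjusted p = 0.0770), that of pgc without unmated replicate 2 or 3 or 6 h replicate 1 or 2 (adjusted p up to 0.105), and that of tor without unmated replicate 1, 3, 4 or 5 or 6 h replicate 1 or 2 (adjusted p up to 0.158). The tor call also ended with the 3' to 5' ratio as a covariate. Without the dimmer probe sets 12 germline genes were left and the list did not pass (adjusted p = 0.149). Chorion and vitelline membrane genes, markers of late follicles, did not pass (19 genes, mean -0.18, adjusted p = 0.975).

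Cell cycle and DNA replication genes were also higher as a list at 6 h (22 genes, mean 1.41, camera adjusted p = 1.51e-07; adjusted p = 0.1001 with an estimated correlation). Mcm2, a subunit of the replicative helicase (log2 change 3.42, SE 0.77), and PCNA, the sliding clamp (2.23, SE 0.45), rose; adjusted over the list alone, 10 rose. The unmated signal of Mcm2 was 7.24, near the floor, and with log2 of signal plus 16 its change was 1.91. The list call rests in part on dim probe sets: without these 10 genes were left and it ended (adjusted p = 0.0549). The call of Mcm2 was lost without unmated replicate 1 or 6 h replicate 1, 2 or 3 (adjusted p up to 0.0951) and that of PCNA without 6 h replicate 1 (adjusted p = 0.0642). The small heat shock genes Hsp26 (5.30, SE 1.08) and Hsp27 (2.03, SE 0.46) rose while their list did not pass (15 genes, adjusted p = 0.123). With log2 of signal plus 16 the change of Hsp26, whose unmated signal was 21.1, was 4.48. Hsp26 was lost without 6 h replicate 1 (adjusted p = 0.0619) and Hsp27 without unmated replicate 1, 3 or 4 or 6 h replicate 1 (adjusted p up to 0.117).

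RpS5b, a ribosomal protein paralogue, rose by 4.06 (SE 1.02, adjusted p = 0.0434), a call lost without any 1 of the 8 arrays (adjusted p up to 0.142). The ribosomal list had a mean of 0.25 (camera adjusted p = 0.0333; adjusted p = 0.779 with an estimated correlation), and its call was lost with quantile normalization (adjusted p = 0.677), without the dimmer probe sets (adjusted p = 0.0951) and without unmated replicate 3 or 4 or 6 h replicate 3 (adjusted p up to 0.442). The ribosomal list call also ended with removal of run 6, with the 3' to 5' ratio as a covariate and without the stray members. Further risen genes were CG14036 (4.83, SE 1.01), CG4570 (4.54, SE 1.04) and the cuticle gene Pcp (2.57, SE 0.44). Unmated signals of CG14036 and CG4570 were 18.8 and 9.01, and with log2 of signal plus 16 their changes were 3.98 and 3.12. CG14036 was lost without 6 h replicate 1 (adjusted p = 0.0699) and CG4570 without unmated replicate 1, 2, 3 or 4 or 6 h replicate 1, 2 or 3 (adjusted p up to 0.0978). The lists of oxidative phosphorylation (72 genes, mean 0.36, adjusted p = 5.77e-07), secretory pathway (42 genes, mean 0.29, adjusted p = 0.000488), proteasome (39 genes, mean 0.21, adjusted p = 0.000747) and glutathione S-transferases (35 genes, mean 0.38, adjusted p = 0.000747) were higher with no member passing. For these lists adjusted p = 0.387, 0.164, 0.156 and 0.0737 with an estimated correlation. Adjusted over the list alone, 6 proteasome genes rose.

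Neuronal genes were lower as a list at 6 h (20 genes, mean -1.17, camera adjusted p = 0.000968; adjusted p = 0.0737 with an estimated correlation); 3 fell, and 6 adjusted over the list alone. These were elav, a neuronal RNA-binding protein (-3.34, SE 0.64, adjusted p = 0.0112), Syn, a synaptic vesicle protein (-3.72, SE 0.77), and nSyb, a vesicle fusion protein (-2.40, SE 0.59). All 3 lay below the array medians of 35.6 to 57.7: the geometric mean signal was 26.7 in unmated females and 2.64 at 6 h for elav, 19.4 and 1.47 for Syn, and 25.6 and 4.85 for nSyb. The sizes of these falls are therefore uncertain. With log2 of signal plus 16 the changes were -1.20, -1.03 and -1.07 (adjusted p = 0.0198, 0.0362 and 0.0650). Without the dimmer probe sets 8 neuronal genes were left and the list did not pass (adjusted p = 0.469). The call of Syn was lost without 6 h replicate 1 or 2 (adjusted p up to 0.0605) and that of nSyb without unmated replicate 2, 3 or 5 or 6 h replicate 1, 2 or 3 (adjusted p up to 0.112). Basement membrane genes were lower (19 genes, mean -0.82, adjusted p = 0.00570; adjusted p = 0.156 with an estimated correlation). Among them Mp, a collagen (-2.84, SE 0.61), and trol, perlecan (-2.05, SE 0.46), fell; Mp had a signal of 13.3 at 6 h and a change of -1.76 with log2 of signal plus 16. Other, dimmer probe sets did not pass: -0.045 and -0.43 for Mp (adjusted p = 0.982 and 0.810) and -1.72 for trol (adjusted p = 0.127). Mp was lost without 6 h replicate 3 (adjusted p = 0.118) and trol without unmated replicate 1 or 3 or 6 h replicate 1 or 3 (adjusted p up to 0.113).

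Hemocyte genes (14 genes, mean -1.21, adjusted p = 0.000719), septate junction genes (22 genes, mean -0.88, adjusted p = 0.00696) and muscle genes (22 genes, mean -0.69, adjusted p = 0.0125) were lower at 6 h with no member passing. For these lists adjusted p = 0.191, 0.420 and 0.394 with an estimated correlation. Adjusted over the list alone, 6, 5 and 2 fell. The septate junction call was lost without unmated replicate 2 or 6 h replicate 3 (adjusted p up to 0.147) and the muscle call without unmated replicate 2 or 6 h replicate 3 (adjusted p up to 0.111). The array 6 h replicate 3 stood apart, at -85.8 on the first principal component against 8.48 and -14.6 for the other 6 h arrays, and had the lowest median signal (35.6). Without it the mean was -0.46 for septate junction, -0.38 for muscle, 0.19 for oxidative phosphorylation and 0.16 for ribosomal genes, each over 1.5 times smaller.

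Immediate early genes (13 genes, mean -0.87, adjusted p = 0.0104) and cytochrome P450 genes (81 genes, mean -0.39, adjusted p = 0.0191) were lower at 6 h too (adjusted p = 0.156 and 0.156 with an estimated correlation). In these lists hry, the repressor Hairy, fell by 2.06 (SE 0.49) and Cyp18a1, which inactivates ecdysone, by 1.96 (SE 0.40). The call of hry was lost without unmated replicate 1, 2, 3 or 4 or 6 h replicate 1 or 3 (adjusted p up to 0.222), that of Cyp18a1 without 6 h replicate 3 (adjusted p = 0.0752), and that of the P450 list without unmated replicate 1 or 6 h replicate 2 (adjusted p up to 0.165). The ecdysone and juvenile hormone list did not pass (31 genes, adjusted p = 0.184), with jhamt risen and Eip93F, an ecdysone-induced transcription factor (-2.58, SE 0.46), and JhI-26 (-1.19, SE 0.30) fallen. Eip93F had a signal of 5.35 at 6 h, and its change was -1.21 with log2 of signal plus 16. The JhI-26 call was lost without any 1 of the 8 arrays (adjusted p up to 0.120).

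The lowest changes at 6 h were those of CG33521 (-4.82, SE 0.86), the receptor phosphatase Ptp99A (-4.26, SE 0.67), CG10077 (-4.13, SE 0.95), lncRNA:CR42862 (-4.01, SE 0.98), the transcription factor REPTOR (-3.82, SE 0.79) and Syn. Other probe sets of Ptp99A had log2 changes of 0.92, -0.88 and -1.45 (adjusted p = 0.598, 0.554 and 0.237), that of CG10077 -1.60 (adjusted p = 0.154) and that of lncRNA:CR42862 -3.92 (adjusted p = 0.0305). The geometric mean signal at 6 h was 6.67 for CG33521, 6.91 for Ptp99A and 8.46 for REPTOR, so the sizes of these falls are uncertain too. With log2 of signal plus 16 they were -2.90, -2.68 and -2.35. CG10077 was lost without unmated replicate 1, 2 or 3 or 6 h replicate 1 or 3 (adjusted p up to 0.184), lncRNA:CR42862 without unmated replicate 1, 2, 3, 4 or 5 or 6 h replicate 3 (adjusted p up to 0.243) and REPTOR without 6 h replicate 2 or 3 (adjusted p up to 0.107). With any 1 array left out, 9 of the 29 named genes stayed past the threshold, among them Send2, jhamt, PGRP-SC2 and elav.

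No run held both unmated and 6 h arrays. Run as a block left 3 probe sets higher and 2 lower, and PGRP-SC2 (3.99, SE 0.52) was the 1 named gene still past the threshold; 256 of the 257 called probe sets kept their sign, and the median SE went from 0.55 to 0.80. In that fit the log2 change was 7.16 for Send2, 6.10 for jhamt, 4.75 for swa and -4.41 for elav, and the list means were 1.20 for germline, 1.00 for cell cycle, -1.11 for neuronal, -0.61 for hemocyte, -0.49 for basement membrane, -0.053 for muscle, -0.13 for septate junction, -0.20 for oxidative phosphorylation and -0.16 for ribosomal genes. The block kept the calls of the germline, cell cycle, proteasome and secretory lists (adjusted p = 0.00922, 0.00922, 0.0298 and 0.0276). It ended those of the neuronal, hemocyte, basement membrane, immediate early, P450, glutathione S-transferase, muscle, septate junction, oxidative phosphorylation and ribosomal lists (adjusted p from 0.0568 for neuronal to 0.797 for septate junction genes). Leaving out an array left 61 higher and 96 lower without unmated replicate 1, 77 higher and 101 lower without replicate 2, 54 higher and 78 lower without replicate 3, 66 higher and 95 lower without replicate 4, 33 higher and 143 lower without 6 h replicate 1 and 52 higher and 43 lower without 6 h replicate 3. Median centring gave 242 higher and 105 lower, quantile normalization 140 and 109, and removal of run 6 63 and 67.

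**Figure D2:**
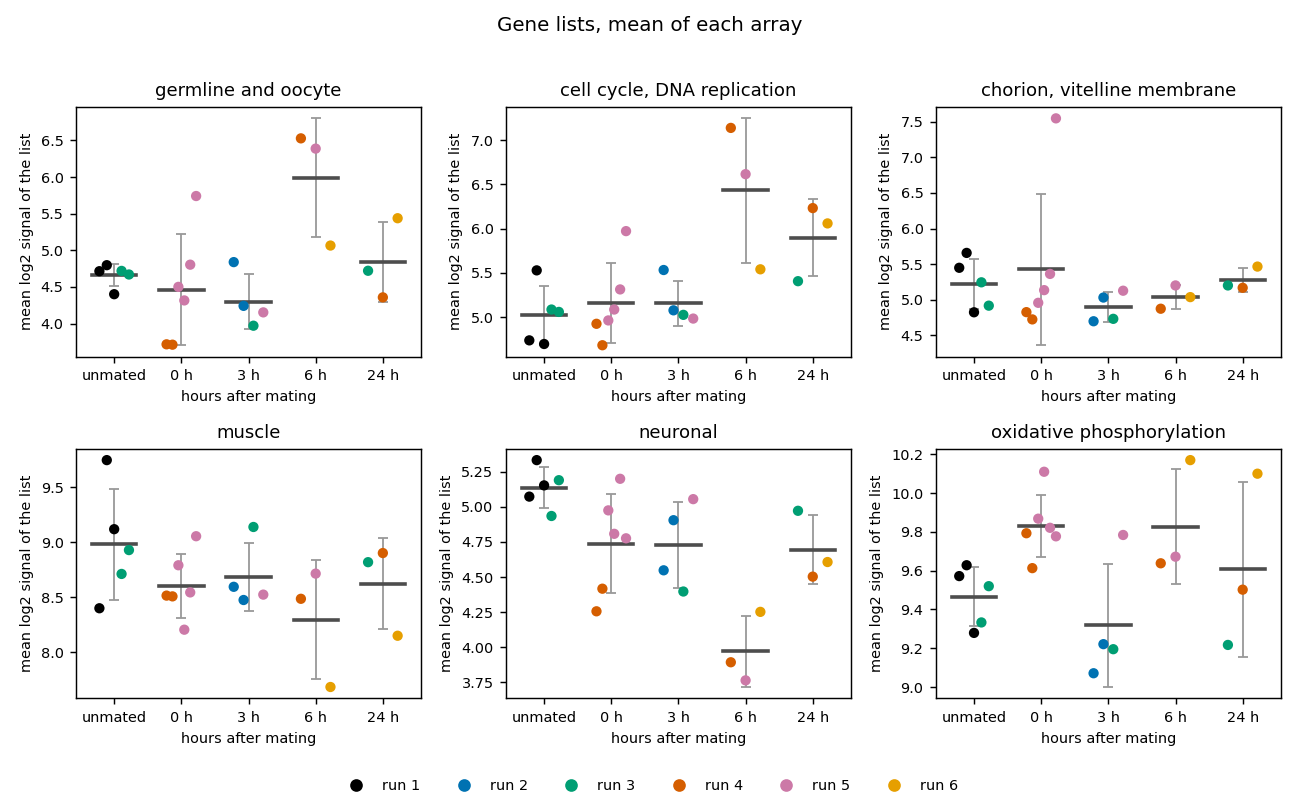
Mean log2 signal (vertical axes) of gene lists by group (horizontal axes); each point is 1 array coloured by processing run, horizontal bars are group means and error bars are SD. The germline list averages 5.99 at 6 h against 4.66 in unmated females.

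At 0 h the log2 change was 2.54 (SE 0.60, adjusted p = 0.385) for Send2 and 2.24 (SE 0.49, adjusted p = 0.310) for jhamt, and -2.49 (SE 0.53, adjusted p = 0.310) for the neuronal gene elav. For the other named genes that rose at 3 h or 6 h it was 1.49 for Mcm2, 1.08 for swa, 0.96 for Pcp, 0.91 for CAH8, 0.82 for PCNA, 0.79 for PGRP-SC2, 0.64 for CG17134, 0.54 for CG14036, 0.49 for CG4570, 0.42 for CG11426, 0.21 for pgc, 0.11 for tor, 0.046 for Hsp26, -0.025 for Hsp27, -0.041 for RpS5b and -0.34 for CG18088. Of genes that fell at 6 h, it was -2.62 for Syn, -2.17 for Ptp99A, -2.12 for REPTOR, -1.75 for CG33521, -1.58 for Eip93F and -1.56 for nSyb. It was smaller for the others: -1.50 for CG10077, -0.81 for Mp, -0.52 for JhI-26 and -0.22 for Cyp18a1. For lncRNA:CR42862, trol and hry the mean log2 signal was 10.22, 7.73 and 10.29 in unmated females and 8.78, 6.73 and 10.32 at 0 h. No probe set passed in limma (0 higher, 0 lower; smallest adjusted p = 0.310), against 1037 at an unadjusted p under 0.05, and without unmated replicate 4 1 was lower. Lists higher at 0 h were oxidative phosphorylation (72 genes, mean 0.36, camera adjusted p = 3.91e-14), ribosomal proteins (38 genes, mean 0.20, adjusted p = 0.00342), proteasome (39 genes, mean 0.15, adjusted p = 0.0124) and glutathione S-transferases (35 genes, mean 0.15, adjusted p = 0.0219), with no member passing. For these lists adjusted p = 0.563, 0.652, 0.638 and 0.507 with an estimated correlation. None passed with run as a block, the means being -0.056, -0.19, 0.13 and 0.19. The ribosomal call was lost without unmated replicate 4 (adjusted p = 0.0647), the proteasome call without unmated replicate 2 (adjusted p = 0.141) and the transferase call without unmated replicate 1 or 5 or 0 h replicate 1 or 2 (adjusted p up to 0.0954). Quantile normalization ended the ribosomal, proteasome and transferase calls (adjusted p = 0.532, 0.124 and 0.0577), so these depend on the scaling. The ribosomal mean was 0.12 without unmated replicate 4 and 0.31 without replicate 2.

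At 24 h the genes that led at 3 h and 6 h had smaller log2 changes, none past the threshold: 0.64 (SE 0.72) for Send2, 0.43 (SE 0.43) for PGRP-SC2, 2.44 (SE 0.59, adjusted p = 0.356) for jhamt and -0.69 (SE 0.55) for CG42284. No probe set passed in limma (0 higher, 0 lower; smallest adjusted p = 0.327), against 1097 at an unadjusted p under 0.05. Without 24 h replicate 1, 9 were higher and 2 lower, and without unmated replicate 2, 2 were lower. Cell cycle and DNA replication genes were higher as a list (22 genes, mean 0.88, camera adjusted p = 8.48e-06), as were glutathione S-transferases (35 genes, mean 0.37, adjusted p = 0.00539) and oxidative phosphorylation (72 genes, mean 0.14, adjusted p = 0.0133), and glycolysis was lower (11 genes, mean -0.43, adjusted p = 0.0402). For these lists adjusted p = 0.314, 0.174, 0.966 and 0.403 with an estimated correlation. The means were 0.69, 0.26, -0.25 and -0.48 with run as a block, which turned the oxidative phosphorylation list downwards, and 0.33, 0.26, -0.21 and -0.47 within run 3. The block ended the cell cycle and transferase calls (adjusted p = 0.0562 and 0.549), and so did removal of the dimmer probe sets (adjusted p = 0.197 and 0.151). The transferase call was also lost without 24 h replicate 3 (adjusted p = 0.148), the oxidative phosphorylation call without unmated replicate 3 or 4 or 24 h replicate 3 (adjusted p up to 0.764), the last of which reversed it, and the glycolysis call without unmated replicate 1, 3 or 4 or 24 h replicate 1 or 3 (adjusted p up to 0.116). Quantile normalization ended the oxidative phosphorylation call (adjusted p = 0.0782). Removal of run 6 ended that call and the transferase and glycolysis calls (adjusted p = 0.722, 0.172 and 0.0793). The oxidative phosphorylation mean was -0.11 without 24 h replicate 3 and 0.34 without replicate 1.

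Between 0 h and 3 h, CG18088 (log2 difference 5.44, SE 0.57, adjusted p = 5.81e-05), CG17134 (5.06, SE 0.91) and Send2 (4.67, SE 0.64) rose and CG42284 fell by 5.57 (SE 0.48, adjusted p = 4.73e-06). The sizes are uncertain for CG18088 and CG17134, at signals of 3.14 and 10.4 at 0 h, and for CG42284, at 8.24 at 3 h. With log2 of signal plus 16 the differences were 2.99, 3.69 and -3.99. In all, 7 probe sets were higher and 2 lower, and 5 differed without 0 h replicate 3. Within run 5 the differences were 4.82 for CG18088, 6.96 for CG17134, 5.70 for Send2 and -6.05 for CG42284. They were, with run as a block, 4.29, 5.17, 4.52 and -5.67, and 2 of the 4 stayed past the threshold. The CG17134 call was lost without 0 h replicate 2, 3, 4, 5 or 6 or 3 h replicate 1, 2 or 3 (adjusted p up to 0.197).

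From 3 h to 6 h, CG42284 rose by 4.44 (SE 0.57, adjusted p = 0.00142), and CG14036 (5.35, SE 1.06) and CG18190 (5.18, SE 1.09) rose too. CG18088 (-4.25, SE 0.68), CG33521 (-4.11, SE 0.90) and CG14253 (-3.85, SE 0.54) fell. Each of the 6 was near the floor at 1 of the times: at 3 h the signal was 8.24 for CG42284, 13.1 for CG14036 and 2.53 for CG18190, and at 6 h 7.14 for CG18088, 6.67 for CG33521 and 3.56 for CG14253. Their sizes are uncertain. With log2 of signal plus 16 the differences were, in the same order, 2.93, 4.18, 2.62, -2.62, -2.27 and -1.79. In all, 28 probe sets were higher and 35 lower. Within run 5 the difference was 5.91 for CG42284, 6.25 for CG14036, 4.82 for CG18190, -3.62 for CG18088, -2.27 for CG33521 and -4.64 for CG14253. The call of 1 of the 6 held with run as a block. CG14036 was lost without 3 h replicate 2, 3 or 4 or 6 h replicate 1 or 2 (adjusted p up to 0.117), CG18190 without 3 h replicate 1, 2, 3 or 4 or 6 h replicate 1 or 2 (adjusted p up to 0.132) and CG33521 without 3 h replicate 1, 2, 3 or 4 or 6 h replicate 3 (adjusted p up to 0.181). The count of both directions was 17, 10, 24 and 20 without 3 h replicates 1 to 4 in turn, and 40 without 6 h replicate 1 or 3.

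From 6 h to 24 h, Send2 fell by 6.24 (SE 0.81, adjusted p = 0.00300), CG8180 by 3.64 (SE 0.58, adjusted p = 0.0143) and PGRP-SC2 by 3.47 (SE 0.48, adjusted p = 0.00339). The signal of CG8180 at 24 h was 7.00, and with log2 of signal plus 16 its difference was -2.23. Removal of run 6 ended the Send2 call. In all, 1 probe set was higher and 4 lower. Within runs 4 and 6 the differences were -6.50 and -7.64 for Send2, -4.85 and -1.68 for CG8180, and -3.36 and -2.93 for PGRP-SC2. The CG8180 call was lost without 6 h replicate 1 or 2 or 24 h replicate 2 (adjusted p up to 0.138). Run as a block ended it too (log2 difference -3.23, adjusted p = 0.0589) and kept the other 2 of the 3 calls. The count of both directions was 13 without 6 h replicate 1, 3 without 6 h replicate 2, 11 without 24 h replicate 1 and 3 without 24 h replicate 2. Over the whole course, the 5 genes with the smallest p of the moderated F test were Send2, CG42284, PGRP-SC2, CAH8 and jhamt.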

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

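The tests of explanations for the 3 patterns weighed here were chosen after the result was seen, and the other splits of the arrays were chosen before. The unmated, 0 h and 3 h groups were examined for 1 array far from the others. The groups at 6 h and 24 h, with 3 arrays each, were too small for this check and were left out. Of 162 sets of values, 21 held such an array, where chance gives about 1 in 20. The gap as a share of the range is given for each. In 0 h replicate 6 it was 0.634 for CG42284 and 0.643 for CG33521, which were low, and 0.729 for Hsp26, 0.649 for CG14036 and 0.711 for swa, which were high. Other 0 h arrays were low for CG10077 (replicate 1, 0.787), Mp (replicate 1, 0.878) and the immediate early list (replicate 2, 0.679) and high for Syn (replicate 4, 0.692). Unmated replicate 2 was high for tor (0.850), Mp (0.720) and the secretory list (0.799), and unmated replicate 5 was low for Syn (0.804). At 3 h, replicate 1 was low for Eip93F (0.847) and high for the cell cycle list (0.831). Replicate 3 was high for tor (0.867) and CG8180 (0.933) and low for the basement membrane list (0.840). Replicate 4 was high for CG33521 (0.861) and low for PCNA (0.864) and the secretory list (0.884).

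Changes against unmated females differed between neighbouring times in 45 tests of the difference itself. From 0 h to 3 h the log2 difference was 4.67 for Send2, 5.06 for CG17134, 5.44 for CG18088, 2.82 for CAH8, 2.70 for CG11426, -5.57 for CG42284 and 2.28 for PGRP-SC2. It was -0.54 for the ribosomal list, -0.51 for oxidative phosphorylation and -0.55 for male accessory gland genes, against 0.047, -0.11 and -0.23 within run 5. Run as a block ended these list calls. Of the gene calls it kept those of CG18088, CG42284 and PGRP-SC2. It ended those of Send2, CG17134, CAH8 (adjusted p = 0.0802) and CG11426 (adjusted p = 0.0515). From 3 h to 6 h the log2 difference was -4.25 for CG18088, -3.68 for CAH8, 4.44 for CG42284, 5.35 for CG14036, -4.11 for CG33521, -3.73 for Ptp99A, -3.83 for REPTOR, 2.45 for tor, 2.28 for Hsp27 and -2.33 for hry. For lists it was 0.59 for ribosomal, 0.51 for oxidative phosphorylation, 0.24 for proteasome, 0.45 for glutathione S-transferase, 1.69 for germline and 1.28 for cell cycle genes. It was -0.76 for neuronal, -1.002 for hemocyte, -0.80 for immediate early, -0.23 for P450, -0.58 for basement membrane and -0.72 for septate junction genes. Within run 5, with 1 array at each time, it was -0.14 for ribosomal, -0.11 for oxidative phosphorylation, -0.018 for proteasome, 0.25 for transferase, 2.24 for germline, 1.63 for cell cycle, -1.29 for neuronal, -0.15 for hemocyte, -0.52 for immediate early, -0.12 for P450, -0.31 for basement membrane and 0.24 for septate junction genes. With run as a block the germline, cell cycle, neuronal and immediate early calls held and those of the other lists ended. Of the gene calls, CAH8 and CG42284 held. Most of the others ended, among them CG18088, CG14036, CG33521 and Hsp27 (adjusted p = 0.268, 0.295, 0.156 and 0.316). Removal of the dimmer probe sets ended the neuronal list call. The 3' to 5' covariate ended the basement membrane call, and removal of run 6 the septate junction call. Calls were also lost for neuronal genes without 6 h replicate 2 (adjusted p = 0.0581), transferases without 6 h replicate 3 (adjusted p = 0.0511), P450 genes without 3 h replicate 4 or 6 h replicate 2 (adjusted p up to 0.175), basement membrane genes without 6 h replicate 3 (adjusted p = 0.0512) and septate junction genes without 6 h replicate 3 (adjusted p = 0.133). From 6 h to 24 h it was -6.24 for Send2 and -3.47 for PGRP-SC2. For lists it was -0.22 for oxidative phosphorylation, -0.12 for proteasome, -0.22 for secretory, -1.16 for germline, -0.53 for cell cycle and -0.32 for glycolysis genes. It was 0.72 for neuronal, 0.94 for hemocyte, 0.60 for immediate early, 0.37 for P450 and 0.55 for septate junction genes. Runs 4 and 6 held 1 array of each time and disagreed for some lists: it was -0.14 and -0.073 for oxidative phosphorylation, -0.34 and 0.0081 for proteasome, -0.011 and -0.24 for secretory, -2.17 and 0.37 for germline, -0.91 and 0.52 for cell cycle, -0.11 and -0.44 for glycolysis genes, and 0.61 and 0.35 for neuronal, 0.90 and 0.84 for hemocyte, 0.75 and 0.75 for immediate early, 0.32 and 0.27 for P450 and 0.73 and 0.63 for septate junction genes. With run as a block the oxidative phosphorylation, cell cycle, glycolysis and P450 calls ended. Removal of the dimmer probe sets ended the neuronal, cell cycle and immediate early calls. The 3' to 5' covariate ended the septate junction call, and removal of run 6 the secretory and glycolysis calls. Calls were also lost for cell cycle genes without 6 h replicate 1 or 24 h replicate 1 (adjusted p up to 0.517), proteasome genes without 6 h replicate 1 or 3 or 24 h replicate 2 (adjusted p up to 0.266), septate junction genes without 6 h replicate 3 or 24 h replicate 1 or 2 (adjusted p up to 0.610) and glycolysis genes without 6 h replicate 3 or 24 h replicate 1 or 3 (adjusted p up to 0.238). The same held for neuronal genes without 6 h replicate 1 or 2 or 24 h replicate 1 (adjusted p up to 0.102), oxidative phosphorylation without 6 h replicate 3 or 24 h replicate 1 (adjusted p up to 0.741), immediate early genes without 6 h replicate 1 or 24 h replicate 2 (adjusted p up to 0.103) and P450 genes without 6 h replicate 2 (adjusted p = 0.0718). Quantile normalization ended the accessory gland call from 0 h to 3 h and the proteasome and glycolysis calls from 6 h to 24 h (adjusted p = 0.0844, 0.0813 and 0.0882). The list differences are camera calls, none of which held with an estimated correlation (smallest adjusted p = 0.551, 0.0935 and 0.169 with an estimated correlation for the 3 intervals). Fry passed 0 of 32 lists from 0 h to 3 h, 8 from 3 h to 6 h and 2 from 6 h to 24 h.

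Other splits of the arrays show how often a random grouping called as many probe sets or lists. They exchange arrays freely across processing runs and so say nothing about run. Arrays of 1 run correlated at 0.311, so arrays are not exchangeable, and a small share of splits does not exclude chance. With run as a block 8 probe sets were higher and 4 lower at 3 h, 3 higher and 2 lower at 6 h, 3 differed between 0 h and 3 h and 3 between 3 h and 6 h. At 3 h the real split called 16 probe sets and the highest other 13 (1 of 100 as large, the real one counted). At 6 h the real split called 257 and the highest other 26 (1 of 56). Between 0 h and 3 h the real split called 9 and the highest other 11 (2 of 100). Between 3 h and 6 h it called 63 and the highest other 5 (1 of 35). The highest other split at 6 h set unmated replicates 1 to 3, which are run 1, against the rest. At 0 h (100 of 100 splits gave as many; highest other 3) and 24 h (56 of 56 splits gave as many; highest other 6) the real count was 0, which every split reaches, so the splits say nothing about chance there. Between 6 h and 24 h the 10 splits are too few for a share under 0.05; the real split gave 5, the highest other 34, and 3 gave as many. For lists, the real split at 6 h called 14 and the highest other 11 (1 of 56 as large). There run as a block left 5 lists and an estimated correlation 0 of 32. Many splits called as many lists at 0 h (4, highest other 9, 33 of 100) and 3 h (3, highest other 8, 38 of 100). The same held at 24 h (4, highest other 10, 21 of 56).

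Germline genes were higher at 6 h (mean log2 change 1.33, SE 0.47). Single arrays of other times reached the level of 6 h replicate 3, whose mean log2 signal of the list was 5.07: it was 5.74 in 0 h replicate 6 and 5.44 in 24 h replicate 3. The log2 signal in these 3 arrays was 6.74, 7.33 and 7.24 for swa, 7.24, 7.68 and 7.58 for pgc, and 8.08, 8.87 and 8.88 for CG14036. The chorion list was at 7.55 in 0 h replicate 6, above the other arrays. Late follicles carried along in the dissection would bring chorion transcripts, whose list was at -0.18 (SE 0.18), which argues against follicles making chorion. Younger egg chambers, which make none, were not tested and stay open. A single 6 h array as the source is argued against by the shift over other genes, which was at least 1.25 with any 1 of the 6 h arrays left out. Maternal RNA of mature eggs in the tract may be a source, but the test does not settle it. Late maternal genes whose own values had not been seen exceeded early germline genes by 1.66 (SE 0.30). These late genes belong to the germline or cell cycle lists, already seen to rise at 6 h. The early genes Sxl, mei-P26, fs(1)Yb and stwl belong to neither list. The choice of members can therefore account for part of the gap. Both sets had exceptions: the late genes stau (-0.39), gnu (0.55), gcl (0.80) and png (0.87) lay low, the early genes zpg (2.48, SE 0.87) and orb (1.80, SE 1.27) lay above 0 without passing, and mei-P26 (-2.79) lowered the early mean. Processing run cannot be told apart from mating here. With run as a block the germline mean was 1.20 and camera still passed (adjusted p = 0.00922), but its SE over arrays rose to 0.73, and no run held both groups. A response of the tract itself stays open as well.

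The 163 probe sets lower at 6 h had a median log2 change of -2.40. RNA integrity as the whole cause is argued against, but weakly: with the 3' to 5' ratio as a covariate the median was -2.31. The probe sets were chosen for falling in the same arrays, which favours a kept fall. The ratio also differed between the runs of the unmated arrays, with means of 2.60 in run 1 and 5.36 in run 3. Even dilution by RNA of another source as the whole cause is not excluded, though the mean gap leaned against it. Brighter probe sets called lower without 1 array of each group fell in the 2 arrays left out by a mean of 1.38 (SE 0.20). This exceeded the fall of the muscle list there by 0.70 (SE 0.31) over 15 such pairs, though in 1 pair or more the muscle list fell further (smallest gap -0.33). The pairs reuse 3 arrays at 6 h and 5 unmated arrays, too few for a gap of this size to decide. Processing run cannot be told apart from mating here: with run as a block the median was -1.73, the median SE of all probe sets went from 0.55 to 0.80 and the residual degrees of freedom from 16 to 11. Each part ended calls: of the 257 in both directions, at an unchanged p, 109 stayed with the log2 change alone replaced, 63 with the SE alone, 180 with the degrees of freedom alone and 15 with all 3; adjusted anew, 3 stayed. A response to mating stays open as well.

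Oxidative phosphorylation and ribosomal lists were higher at 0 h, by 0.36 and 0.20. With run as a block the means were -0.056 and -0.19, so processing run may account for the rise. No run held both groups, and the median SE of all probe sets went from 0.46 to 0.78. Run and mating therefore cannot be told apart here. With the 3' to 5' ratio as a covariate the oxidative phosphorylation mean was 0.31 (SE over arrays 0.15). This argues against RNA integrity as the whole cause for that list, by little more than 2 SE. Camera gave adjusted p = 1.12e-12 in that fit, which does not measure the spread over arrays. For the ribosomal list integrity stays open, at 0.13 (SE over arrays 0.20, camera adjusted p = 0.0214). With quantile normalization the ribosomal call ended (adjusted p = 0.532) and that of oxidative phosphorylation held (adjusted p = 3.97e-06). A response to mating was not separated from these.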

How the results depend on the processing

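Log2 of signal plus 16, the 3' to 5' covariate, removal of run 6 and the lists without strays were chosen after seeing the data. Counts that moved by more than 1.5 times are given by setting; the cause was not tested except where fewer probe sets or arrays were used. Run as a fixed block gave 1 higher at 0 h, 1 lower at 0 h, 3 higher at 6 h, 2 lower at 6 h, 4 higher at 24 h, 6 lower at 24 h, 3 differing between 0 h and 3 h, 3 differing between 3 h and 6 h, 0 lists at 0 h, 0 lists at 3 h and 5 lists at 6 h. With array weights there were 31 higher at 3 h, 41 lower at 3 h, 6 higher at 24 h, 1 lower at 24 h, 138 differing between 0 h and 3 h, 109 differing between 3 h and 6 h and 13 differing between 6 h and 24 h. With 1 probe set per gene there were 3 lower at 3 h. With only the groups compared there were 2 lower at 3 h, 32 higher at 6 h, 28 lower at 6 h, 6 differing between 3 h and 6 h and 0 differing between 6 h and 24 h. With median centring there were 242 higher at 6 h and 105 lower at 6 h. Without the dimmer probe sets there were 176 higher at 6 h, 251 lower at 6 h and 17 differing between 0 h and 3 h. Run as a random block gave 24 higher at 6 h, 41 lower at 6 h, 19 differing between 3 h and 6 h and 10 differing between 6 h and 24 h. With a variance trend and robust moderation there were 174 higher at 6 h, 253 lower at 6 h and 18 differing between 0 h and 3 h. With log2 of signal plus 16 there were 248 higher at 6 h, 259 lower at 6 h, 1 higher at 24 h, 22 differing between 0 h and 3 h, 142 differing between 3 h and 6 h and 8 differing between 6 h and 24 h. With the 3' to 5' ratio as a covariate there were 154 higher at 6 h. Without run 6 there were 67 lower at 6 h, 3 differing between 6 h and 24 h and 2 lists at 24 h. With an estimated correlation there were 0 lists at 0 h, 0 lists at 3 h, 0 lists at 6 h and 0 lists at 24 h. With fry there were 0 lists at 0 h, 0 lists at 3 h and 0 lists at 24 h. At 6 h fry passed 13 of 32 lists. It ended the ribosomal, oxidative phosphorylation and septate junction calls there. With quantile normalization there were 0 lists at 3 h. A 1.5-fold minimum moved no count by that much.

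With 1 array left out the counts ranged over 0 to 0 higher at 0 h, 0 to 1 lower at 0 h, 3 to 6 lists at 0 h, 7 to 12 higher at 3 h, 3 to 6 lower at 3 h, 1 to 6 lists at 3 h, 33 to 113 higher at 6 h, 43 to 184 lower at 6 h, 12 to 15 lists at 6 h, 0 to 9 higher at 24 h, 0 to 2 lower at 24 h, 2 to 8 lists at 24 h, 5 to 11 differing between 0 h and 3 h, 10 to 49 differing between 3 h and 6 h and 3 to 13 differing between 6 h and 24 h. The list count at 3 h was 1 without unmated replicate 5 and 6 without 3 h replicate 3, and at 24 h 2 without unmated replicate 4 or 24 h replicate 3 and 8 without 24 h replicate 2.

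These lists reversed with run as a block: ribosomal proteins at 0 h (adjusted p = 0.596), muscle contractile apparatus at 6 h (adjusted p = 0.726), ribosomal proteins at 6 h (adjusted p = 0.269), oxidative phosphorylation at 6 h (adjusted p = 0.371), septate junctions at 6 h (adjusted p = 0.797), oxidative phosphorylation at 24 h (adjusted p = 0.0140), cuticle proteins at 3 h against 0 h (adjusted p = 0.906), ribosomal proteins at 3 h against 0 h (adjusted p = 0.639), ribosomal proteins at 6 h against 3 h (adjusted p = 0.210) and oxidative phosphorylation at 6 h against 3 h (adjusted p = 0.670). The oxidative phosphorylation list at 24 h also reversed without run 6 (adjusted p = 0.722) and without 24 h replicate 3 (adjusted p = 0.764, the highest with 1 array left out, the lowest being 8.88e-07 without 24 h replicate 1). Other probe sets of 3 named genes went the other way: CG42284 at 3 h (0.33) and from 3 h to 6 h (-0.14), Ptp99A at 6 h (0.92) and swa at 6 h (-0.67); the cause was not tested. Of the named-gene calls, 12 kept their side of the threshold and 40 did not with run as a fixed block, 26 and 26 with run as a random block and 26 and 26 with only the groups compared (from 6 h to 24 h 0 of 3 were kept), against 49 and 3 with quantile normalization. With the 3' to 5' ratio as a covariate 48 named-gene calls kept their side and 4 did not. These were tor and RpS5b at 6 h, and CG18190 and CG33521 from 3 h to 6 h. Low signal limits what can be read for genes near background, where log2 values of single arrays scatter most.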

Other observations

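The tests of overlap between 3 h and 6 h were chosen after the result was seen. Several lists fixed beforehand stayed short of the threshold at 3 h and at 6 h in camera. Antimicrobial peptides had a mean log2 change of -0.084 at 3 h (adjusted p = 0.878) and 0.064 at 6 h (adjusted p = 0.975), with medians of -0.28 and -0.30. Immune recognition genes were at 0.15 (adjusted p = 0.169) and -0.25 (adjusted p = 0.550), PGRP-SC2 being their 1 member past the threshold at either time. Testis and sperm genes were at -0.41 (adjusted p = 0.359) and -0.11 (adjusted p = 0.975), and receptors and enzymes of monoamine and egg-laying signalling at -0.36 (adjusted p = 0.550) and -0.41 (adjusted p = 0.336).

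The 3 h and 6 h comparisons use the same unmated arrays, which alone makes their changes correlate. They shared 7 higher probe sets and 1 lower. Independent lists of these sizes would share 0.0740 and 0.0584. In 50 simulations of unchanged groups with shared controls the means were 0 and 0, but such groups give hardly any calls to share, so these counts do not show what the shared arrays add. Over 20 splits that gave each time its own unmated arrays, the median number shared was 4 higher (3 to 6) and 0 lower. Each time then had fewer unmated arrays, which alone can lower the number called. The drop therefore does not measure what the shared arrays add. Over all probe sets the log2 changes at 3 h and 6 h correlated at 0.426, near the 0.409 simulated with no change. Their covariance was 0.239 against 0.151 simulated, and 0.0914 at the median with split controls. The simulation had independent noise and no processing run. Its values therefore do not show whether 3 h and 6 h share a response.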
